A study of Mus musculus with 48 samples.

How the data were processed

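The 48 libraries came from neuron-enriched cultures of adult wild-type mouse dorsal root ganglion (DRG), the ganglion that holds the cell bodies of sensory neurons. Per the labels, cells were dissociated and transfected at once with a pool of siRNAs or with synthetic mRNA, RNA was taken 42 h later, and libraries were made with a stranded poly(A) kit. An untransfected group was taken at time 0. The 12 groups held 4 libraries each, and each library was placed in its group by its treatment label. The labels do not say whether replicates were separate animals or separate cultures, so p-values measure the spread between these samples, which can be technical. The siKlf6 libraries carry the replicate numbers 1, 2, 4 and 5.

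The authors deposited 1 table for the siRNA and time 0 libraries and 1 for the mRNA libraries, each with 34183 genes. The deposited values are expected counts per gene (estimated counts that need not be whole), made with kallisto against GRCm39 per the submitters' processing notes. The kallisto version, the annotation release and the scaling step are not given in the sources used here. The form of the values was therefore read from the tables, where small values were multiplied by transcript length in those of 3003 single-transcript genes of at least 2000 bp that had one. In each library these products were most frequent near 1 constant, between 1930 and 2230 bp, with 169 to 296 of 295 to 556 genes within 4% of it and the others further off. The expected counts were therefore taken to be weighted by transcript length, as counts derived from TPM are: a read in a short transcript would add more than a read in a long one. Such a weight is the same for a gene in every library of a comparison, apart from shifts between its isoforms, so fold changes keep their meaning. The count model does not know such a weight, so the counting error it assumes is too small for short genes and too large for long ones, and the spread between libraries, which the test estimates from the data, takes up part of the difference. Levels in CPM (counts scaled to a common library total) are on the scale of the deposited values.

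All 48 columns were matched to a sample by name, 0 columns were left unused and 0 pairs of columns were identical. Column totals ranged from 1539198 to 6621566. Gene symbols and transcript lengths were taken from GENCODE annotation of the older mouse build GRCm38, which gave a symbol to 32470 of the 34183 gene identifiers (95%). No coordinates were used, since the builds differ. Some symbols are older forms, such as Aars and Cars for the alanyl and cysteinyl tRNA synthetases.

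Expected counts were rounded to whole numbers. Genes were kept by filterByExpr with the group as factor, libraries were scaled by TMM, and groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. All adjusted p for genes are from that test with Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. The 7 knockdowns and siCONTROL were fitted together (14876 genes) and share 1 estimate of the spread. The 3 mRNA groups were fitted together (13857 genes). The change in culture was fitted with time 0 and siCONTROL alone (13448 genes). Fold changes are edgeR estimates with their standard errors (SE), and levels are mean CPM with the standard deviation (SD) over 4 libraries. Intervals on shares of genes treat genes as independent, which they are not. Where every library of a group held 0 counts, a fold is given as a lower bound against a floor of 3 reads over the whole group. All genes were counted against transcripts, so members of near-identical families, such as the Mrgpr receptors, the hemoglobins and the Ifit genes, can exchange reads.

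Before the data were examined, 26 gene lists were fixed: 16 pathway lists and 10 lists of cell type or RNA quality markers. Of 406 genes in them, 403 were found. Ddit3, Ddx39a and Zc3h11a were not matched by symbol and are not analysed here. Each list with at least 5 genes tested was compared with all other genes by camera in limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 265 tests. The tests were repeated with the correlation estimated per list, with the replicate number as a block, with fry, and with the targeted genes left out of every list. Of 63 tests past the threshold with the preset correlation, 13 also passed with an estimated correlation: in siAtf4 amino acid synthesis, amino acid transporters, tRNA synthetases, integrated stress response regulators, ER chaperones and cholesterol synthesis, in siAtf3, siJun, siStat3 and culture the regeneration-associated genes, in siAtf3 the amino acid transporters, in siStat3 the STAT3 list, and in culture the apoptosis and p53 targets. Member counts are given over all genes tested and adjusted over the list alone.

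Genes named in the text were chosen by a rule fixed at the same time. They are the targeted or transfected genes, the genes with the largest fold changes among those past the threshold with a mean of at least 5 CPM and no overlap between the values of the groups compared, and up to 4 members of each list with the smallest p. The first kind takes up to 10 genes in each direction for siAtf4, for both mRNA comparisons with GFP and for culture, and up to 5 for the others. Predicted genes, Rik clones and pseudogenes were passed over. Any other gene is said to have been chosen after its values were seen.

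Comparisons that share control libraries were set beside 20 simulations of unchanged groups against those controls, beside the overlap of independent lists, and beside values with the 4 controls split over their 3 divisions into pairs. The edgeR step was tested on simulated counts drawn at the means, library sizes and spread of the real libraries. For siAtf3 it recovered 43.3% of genes changed 1.5-fold, 62.7% at 2-fold and 89.4% at 4-fold, with 1 false call among 14602 genes. For Atf4 mRNA these shares were 22.4%, 50.7% and 90.9%, with 8 false calls among 13598 genes, and for culture 26.9%, 64.2% and 90.9%, with 9 among 13122. Of 200 random lists, camera gave an unadjusted p under 0.05 to 7 for siAtf3, 6 for Atf4 mRNA and 7 for culture. Genes were drawn independently there, so this does not test the preset correlation on lists whose genes move together.

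The alternatives were median-ratio size factors, no filter, a filter of at least 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, and leaving out each replicate in turn. Chosen after seeing the data were a term for replicates 1 and 2 against the others, a fit without the shallowest siKlf6 and siRest libraries, a fit without Atf4 and Cebpg in the scaling, and the lists without targeted genes. Sequences of the transfected mRNAs and of the siRNAs were not used here.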

Results

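RNA was sequenced from cultures of adult mouse dorsal root ganglion (DRG) enriched for sensory neurons. Dissociation cuts the axons of these neurons, which then regrow neurites in the dish. The series asked what the transcription factors Atf3, Atf4, Jun, Stat3, Klf6 and Rest, and the mRNA export factor Alyref, contribute to gene expression in that state. Each was knocked down by a pool of siRNAs given right after isolation, and cells were harvested 42 h later beside cells given a control pool (siCONTROL). Other cultures received synthetic mRNA for Atf4, for Atf4 with its dimer partner Cebpg, or for green fluorescent protein (GFP). A further group was taken untransfected at time 0. Each of the 12 groups had 4 libraries, 48 in all, with 1539198 to 6621566 counts per library. The shallowest library of the series belonged to siKlf6 and the next to siRest.

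Every targeted transcript was lower in its own group, with no overlap with the 4 siCONTROL libraries. By the edgeR fold change, Atf3 fell to 17.4% of control (216 ± 36.2 against 1246 ± 109 CPM, mean ± SD, n = 4, log2 fold change -2.53 ± 0.0991 SE, adjusted p = 2.35e-17). Atf4 fell to 16.8% (96.2 ± 23.9 against 574 ± 37.2 CPM, adjusted p = 8.28e-14) and Stat3 to 17.3% (47.3 ± 10.4 against 273 ± 12.2 CPM, adjusted p = 2.65e-18). Alyref fell to 21.7% (adjusted p = 7.84e-11), Klf6 to 22.6% (adjusted p = 4.69e-14) and Jun to 29.8% (adjusted p = 2.1e-14). Rest, which was scarce in control cultures (8.46 ± 0.817 CPM), fell to 36.3% by the edgeR fold change (3.30 ± 1.35 CPM, adjusted p = 0.000146). With Rest and control libraries fitted alone, Rest had a log2 fold change of -1.45 and an adjusted p of 0.275. Transcript levels say nothing of protein, which was not measured here. Each target had 1 siRNA pool, so loss of the target and other effects of its pool are not separated in any knockdown.

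Klf6 was also lower when other factors were targeted: 1.30-fold with siAtf3 (adjusted p = 0.00769), 1.32-fold with siJun (adjusted p = 0.00724), 1.36-fold with siStat3 (adjusted p = 0.00595) and 1.40-fold with siAlyref (adjusted p = 0.00201). Atf3 was 1.26-fold lower with siStat3 (adjusted p = 0.0399). These 5 comparisons share the same 4 control libraries, so they are not independent of each other.

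**Figure D1:**
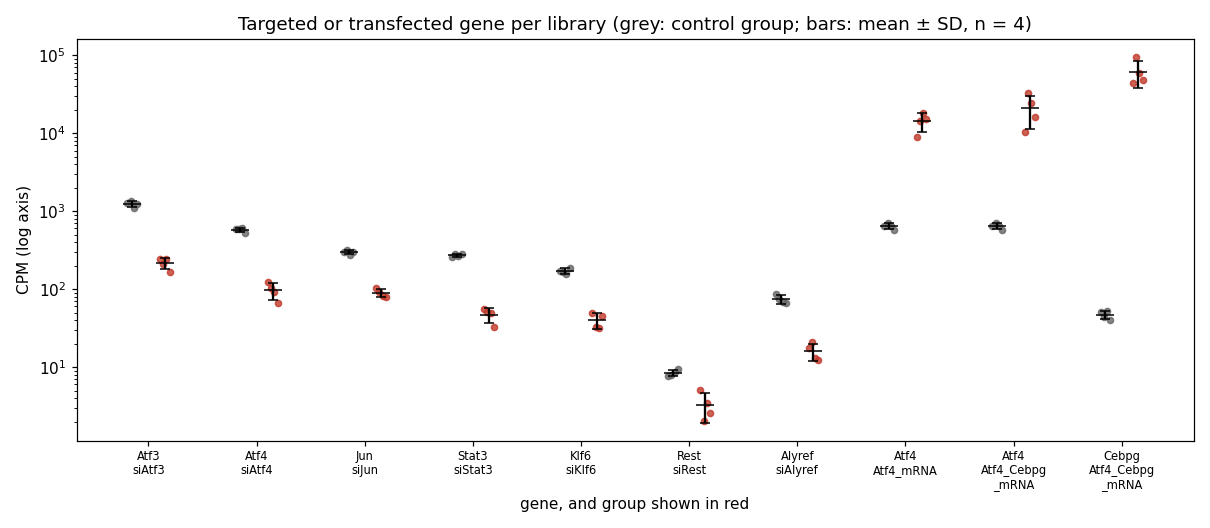
Level of each targeted or transfected gene in CPM on a log axis, with 1 point per library. Grey points are control libraries and red points the knockdown or mRNA group; bars show mean ± SD of 4 libraries.

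Time in culture was the largest change in the series. Between time 0 and siCONTROL at 42 h, 3855 genes rose and 3926 fell of 13448 tested, and 1456 rose and 1803 fell at least 2-fold. Genes induced by nerve injury were among those with large rises: Sprr1a, a small proline-rich protein that promotes neurite outgrowth, went from 0.491 to 316 ± 50.2 CPM (628-fold, adjusted p = 8.57e-10), and Ecel1, an injury-induced endopeptidase, from 0.907 to 198 CPM (214-fold, adjusted p = 7.62e-10). Atf3 itself rose 6.27-fold (189 ± 10.1 to 1187 ± 102 CPM, adjusted p = 1.32e-09). Receptors that mark itch and pain neurons were lost: Mrgprd fell 141-fold (166 to 1.18 CPM, adjusted p = 2.3e-10), Mrgpra3 went from 40.2 to 0.122 CPM, and Mrgprx1, Mrgprb4 and Mrgpra2a, at 0 counts in every siCONTROL library, fell at least 154-fold, 120-fold and 60.0-fold.

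Of the other genes with the largest rises under the naming rule, Star, a cholesterol carrier of mitochondria, rose 170-fold (adjusted p = 1.22e-07). The metalloproteinase Mmp12 went from 0.106 to 29.5 CPM and the cystine transporter Slc7a11 from 0.0527 to 12.6 CPM. Mmp3 (at least 189-fold), Colec10 (at least 112-fold), Dusp9 (at least 82.1-fold), Adm2 (at least 55.3-fold) and Csrp3 (at least 41.9-fold) had 0 counts at time 0. Among those that fell were the nicotinic receptor subunit Chrna6 (68.1-fold, adjusted p = 1.4e-09), A3galt2 (67.2-fold), Sfrp5 (56.7-fold), Ms4a3 (at least 42.7-fold) and the antigen-presentation gene H2-Aa (17.4 to 0.259 CPM). Of the other targeted genes, Rest rose 4.42-fold, Klf6 2.73-fold, Cebpg 2.62-fold, Alyref 2.57-fold and Atf4 2.47-fold, while Jun (adjusted p = 0.448) and Stat3 (adjusted p = 0.0784) did not pass.

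Of 24 regeneration-associated genes tested, 21 rose with culture (21 up and 1 down adjusted over the list alone), among them Tnfrsf12a 25.7-fold, Stmn4 14.4-fold and Flrt3 12.1-fold; the median log2 fold change was 2.77 (camera adjusted p = 3.01e-10). Apoptosis and p53 target genes rose in 13 of 17 and fell in 1 (14 and 1 over the list alone), with Cdkn1a, the cell cycle inhibitor p21, up 13.3-fold, Phlda3 5.39-fold, Mdm2 5.26-fold and Bax 2.46-fold (camera adjusted p = 1.18e-05). With an estimated correlation each of these lists had adjusted p = 0.0389.

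Genes of amino acid supply rose as well, and list-alone counts equal those given here. Amino acid synthesis genes rose in 12 of 13 (Psat1 4.67-fold, Mthfd2 4.37-fold, camera adjusted p = 8.22e-05, adjusted p = 0.0930 with an estimated correlation), amino acid transporters in 8 of 10 with 1 lower (Slc7a5 3.66-fold, Slc38a1 3.76-fold, camera 0.00323, adjusted p = 0.128 with an estimated correlation) and cytosolic tRNA synthetases in 19 of 20 (Aars 3.20-fold, Cars 3.40-fold, camera 2.3e-07, adjusted p = 0.145 with an estimated correlation). Integrated stress response regulators, a list that holds Atf3, rose in 13 of 15 with 1 lower (Chac1 10.7-fold, Sesn2 10.4-fold, camera 4.44e-05, adjusted p = 0.243 with an estimated correlation). ER chaperones and degradation genes rose in 12 of 16 with 1 lower (Hspa5 2.24-fold, camera 0.00595, adjusted p = 0.247 with an estimated correlation).

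Genes of mature neuronal function mostly fell. Voltage-gated ion channels fell in 21 of 23 and rose in 1 (Scn11a 17.2-fold, Kcna2 14.8-fold and Scn10a 7.69-fold lower, camera adjusted p = 7.01e-08, adjusted p = 0.165 with an estimated correlation), nociceptor markers fell in 15 of 17 and rose in 1 (2 rose over the list alone, camera 6.16e-07, adjusted p = 0.414 with an estimated correlation) and markers of large-diameter neurons fell in 11 of 12 and rose in 1 (Kcns1 21.5-fold lower, camera 0.00152, adjusted p = 0.652 with an estimated correlation). Pan-neuronal markers fell in 8 of 15 and rose in 1 (Rbfox3 5.35-fold, Syt1 2.46-fold lower, camera 0.0302, adjusted p = 0.652 with an estimated correlation). Neuronal genes with an RE1 site, the element that Rest binds, fell in 17 of 25 and rose in 2 (Scg3 2.87-fold lower, Syt4 4.45-fold higher, camera 0.00141, adjusted p = 0.250 with an estimated correlation). Outside that class, AP-1 and immediate early genes fell in 9 of 16 and rose in 4 (camera 0.0491, adjusted p = 0.728 with an estimated correlation). Fos was 24.9-fold, Fosb 23.3-fold and Egr1 11.5-fold lower. Time 0 is itself labelled a DRG culture, so none of these changes is measured from an intact ganglion.

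Markers of other cells moved too, in both directions, and a change in cell composition was not separated from regulation within cells. Satellite glia markers fell in 7 of 10 and rose in 2 (Fabp7 41.6-fold and Apoe 15.3-fold lower, Sox10 1.89-fold higher, camera adjusted p = 0.0599), and Schwann cell markers fell in 8 of 12 and rose in 2 (Ngfr 2.77-fold and Mag 12.03-fold lower, camera 0.0705). Fibroblast markers rose in 4 of 8 and fell in 2 (Postn 3.38-fold higher, Apod 5.66-fold lower, camera 0.637), endothelial and mural markers rose in 5 of 10 and fell in 2 (Pecam1 5.34-fold higher, camera 0.461), and of 5 macrophage markers 2 rose and 2 fell (3 over the list alone, Cd68 35.8-fold higher, C1qa at least 12.1-fold lower, camera 0.827). All 4 red cell markers fell (Hbb-bs 50.2-fold; too few genes for a set test), and mitochondrially encoded genes fell in 9 of 13 (mt-Co1 2.19-fold, camera 0.0102, adjusted p = 0.750 with an estimated correlation). All 6 cell cycle genes tested rose (Rrm2 14.0-fold, Cdk1 13.3-fold, camera 0.00948, adjusted p = 0.387 with an estimated correlation).

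The other lists did not pass as sets. Cholesterol synthesis genes fell in 12 of 20 and rose in 2 (Insig1 1.59-fold higher, camera adjusted p = 0.0626), interferon response genes fell in 7 of 17 and rose in 3 (Ifit1 4.28-fold lower, camera 0.210), and STAT3 and cytokine response genes fell in 6 of 16 and rose in 4 (Socs3 3.95-fold lower, Timp1 34.8-fold higher, camera 0.743). TREX mRNA export factors, a list that holds Alyref, rose in 5 of 14 (3 over the list alone, Ddx39b 1.42-fold, camera 0.145), and the KLF family rose in 1 and fell in 4 of 13 (Klf2 3.18-fold lower, camera 0.695). The control cultures were also transfected, so time in culture and transfection cannot be separated here.

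Genes that make, import and charge amino acids were lower with siAtf4. With siAtf4, 408 genes rose and 620 fell of 14876 tested, 49 and 85 of them at least 2-fold. Chac1, which degrades glutathione, fell 6.57-fold (17.1 ± 3.46 against 112 ± 17.1 CPM, log2 fold change -2.72 ± 0.168 SE, adjusted p = 1.45e-12), Adm2 10.7-fold (adjusted p = 1.13e-09), Prr32 6.36-fold, Tmem154 4.32-fold, Mmp19 3.65-fold and the growth factor Vegfa 3.21-fold (19.0 against 60.6 CPM, adjusted p = 2.08e-08). Inhba, the activin A subunit, rose 3.64-fold (223 ± 31.1 against 61.2 ± 11.5 CPM, log2 fold change 1.87 ± 0.173 SE, adjusted p = 6e-09), Pmaip1, which encodes the apoptosis protein Noxa, 2.97-fold (adjusted p = 2.13e-07) and Anxa1 2.51-fold (adjusted p = 2.71e-05). Slc28a2 (3.56-fold), Fndc9 (2.77-fold), Mrnip (2.49-fold), Zfp804a (2.42-fold), Pthlh (2.41-fold), Snhg5 (2.37-fold) and Hoxa4 (2.36-fold) were the other genes with the largest rises under the naming rule.

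All 13 amino acid synthesis genes fell, with a median log2 fold change of -1.37 (camera adjusted p = 7.73e-37). Mthfd2 of mitochondrial folate metabolism fell 3.37-fold (43.4 against 147 CPM, adjusted p = 6.25e-12), Aldh18a1 of proline synthesis 3.26-fold, the serine synthesis enzymes Phgdh 3.01-fold and Psat1 2.68-fold, and asparagine synthetase Asns 2.00-fold (187 against 374 CPM, adjusted p = 6.32e-13). Of 10 amino acid transporters 9 fell (median -0.84, camera 5.09e-22), with Slc7a3 2.78-fold, Slc7a5 2.77-fold and Slc7a1 2.30-fold lower. Cytosolic tRNA synthetases fell in 13 of 20 (15 over the list alone, median -0.66, camera 2.41e-25), with Cars 3.23-fold (adjusted p = 2.69e-13), Wars 1.78-fold and Gars 1.62-fold lower. Integrated stress response regulators fell in 13 of 17 (14 over the list alone, median -0.96, camera 6.99e-23), with Vldlr 2.62-fold, Eif4ebp1 2.23-fold and Sesn2 2.01-fold lower. Many of these genes are textbook targets of Atf4, and the lists were drawn up with that knowledge.

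Cholesterol synthesis genes fell in 12 of 20 (18 over the list alone, median -0.43, camera adjusted p = 3.81e-15), with Mvd 1.70-fold and Hmgcs1 1.39-fold lower. ER chaperones and degradation genes fell in 6 of 16 (10 over the list alone, median -0.27, camera 2.98e-06), among them Herpud1 1.94-fold and Hspa5 1.52-fold. These 6 lists passed with an estimated correlation too, with adjusted p between 3.51e-08 and 0.0160. Regeneration-associated genes rose in 5 of 26 and fell in 1 (8 and 1 over the list alone, Arg1 3.23-fold and Smad1 1.33-fold higher, Tubb6 1.24-fold lower, camera 0.0423, adjusted p = 0.445 with an estimated correlation), and pan-neuronal markers rose in 3 of 15 (Isl1 2.16-fold, Rbfox3 1.55-fold, camera 0.0423, adjusted p = 0.652 with an estimated correlation). Cebpg was at 33.0 ± 5.84 CPM against 46.9 ± 5.95 (adjusted p = 0.438).

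The siAtf3 pool moved more genes than any other knockdown: 595 rose and 1114 fell, 80 and 167 at least 2-fold. Csrp3, the muscle LIM protein, fell 22.2-fold (0.677 against 15.6 CPM, adjusted p = 0.00036), Aim2 3.60-fold, the lipid kinase Pip4k2a 3.56-fold (adjusted p = 1.12e-09) and Fgf3 3.38-fold. The peroxisomal oxidase Acox2 rose 8.88-fold (10.5 against 1.15 CPM, adjusted p = 0.000849), Extl1 4.79-fold, the stress hormone Fgf21 4.16-fold (adjusted p = 0.0106), Cyb5r2 4.11-fold (adjusted p = 3.59e-07) and Prrg4 3.46-fold (adjusted p = 7.45e-08). The difference in number of genes between knockdowns was not tested.

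Regeneration-associated genes, a list that includes Atf3 itself, fell in 15 of 26 with siAtf3 (17 over the list alone, median log2 fold change -0.39, camera adjusted p = 4.39e-11), with Cckbr 2.54-fold, Sprr1a 2.15-fold and Tnfrsf12a 1.43-fold lower; without the targeted genes the adjusted p was 8.41e-09, and with an estimated correlation 0.00329. Pan-neuronal markers fell in 8 of 15 (11 over the list alone, Syt1 1.68-fold, Elavl4 1.52-fold and Rbfox3 1.39-fold lower, camera 9.76e-06, adjusted p = 0.231 with an estimated correlation). Neuronal genes with an RE1 site fell in 7 of 26 and rose in 1 (8 and 1 over the list alone, Chrnb2 1.61-fold lower, camera 0.0185, adjusted p = 0.534 with an estimated correlation). Integrated stress response regulators rose in 8 of 17, and the 1 that fell was Atf3 (11 and 1 over the list alone, Nupr1 2.16-fold, Chac1 1.59-fold and Sesn2 1.52-fold higher, camera 0.00106, adjusted p = 0.254 with an estimated correlation). Of 10 amino acid transporters 2 rose, Slc1a4 1.599-fold and Slc7a1 1.37-fold (4 over the list alone, camera 0.00149, adjusted p = 0.0181 with an estimated correlation). Of 20 interferon response genes 0 passed by edgeR, while the set did by camera (0.0178, adjusted p = 0.822 with an estimated correlation).

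Regeneration-associated genes were mostly lower and 7 of 16 nociceptor markers higher with siJun. As a list, the nociceptor markers did not pass with an estimated correlation (adjusted p = 0.0837). With siJun 474 genes rose and 683 fell, 73 and 94 at least 2-fold. Tac1, the precursor of substance P, rose 4.35-fold (516 ± 94.7 against 119 ± 17.1 CPM, adjusted p = 1.99e-09), the synaptic pentraxin Nptx1 5.11-fold (adjusted p = 3.47e-08), Fgf21 6.50-fold (adjusted p = 0.0013), Cdsn 4.06-fold and B4galnt2 3.10-fold. Pilra fell 6.08-fold, the neuropeptide receptor Qrfpr 4.47-fold (adjusted p = 2.7e-09), Fgf3 4.23-fold, Aim2 4.16-fold and Inhba 3.93-fold (15.6 against 61.2 CPM, adjusted p = 7.23e-08). Inhba had moved the other way with siAtf4.

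Of 26 regeneration-associated genes, including Jun, 16 fell and 1 rose with siJun (19 and 2 over the list alone, median log2 fold change -0.41, camera adjusted p = 1.19e-15, and 0.000385 with an estimated correlation), with Sprr1a 2.96-fold, Tubb6 1.82-fold and Stmn4 1.67-fold lower. Nociceptor markers rose in 7 of 16 (11 over the list alone, median 0.46, camera 1.36e-06, adjusted p = 0.0837 with an estimated correlation), with the sodium channels Scn11a 1.64-fold and Scn10a 1.44-fold and the peptide precursor Calca 1.30-fold higher. Voltage-gated ion channels, which share Scn10a and Scn11a with that list, rose in 6 of 23 and fell in 2 (9 and 2 over the list alone, camera 0.0185, adjusted p = 0.534 with an estimated correlation). Integrated stress response regulators rose in 5 of 17 (6 up and 1 down over the list alone, Gdf15 1.68-fold, camera 0.00323, adjusted p = 0.331 with an estimated correlation) and amino acid transporters in 3 of 10 (4 over the list alone, Slc1a4 1.38-fold, camera 0.0245, adjusted p = 0.0952 with an estimated correlation). Cell cycle genes fell in 1 of 12 (Cdk1 2.45-fold, median -0.69, camera 0.00639, adjusted p = 0.331 with an estimated correlation). Of the interferon response genes 0 of 20 passed by edgeR (camera 0.0351, adjusted p = 0.841 with an estimated correlation).

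With siStat3 a feedback inhibitor of the pathway was lower and 17 of 20 interferon response genes were higher. As a list, the interferon genes did not pass with an estimated correlation (adjusted p = 0.0506). With siStat3 177 genes rose and 273 fell, 72 and 43 at least 2-fold. Socs3, the suppressor induced by STAT3, fell 2.89-fold (10.9 against 31.5 CPM, adjusted p = 8.08e-08), the activin subunit Inhbb 6.11-fold (adjusted p = 0.000298), the steroid sulfate carrier Slc10a6 3.45-fold, Mettl7a3 3.17-fold and Prokr2 3.11-fold. Iigp1, an interferon-inducible GTPase, rose 19.8-fold (27.8 ± 7.05 against 1.33 ± 0.775 CPM, adjusted p = 1.69e-08), Ifit1 18.5-fold (84.2 ± 58.9 against 4.46 ± 1.22 CPM, adjusted p = 0.00033), Gbp6 13.03-fold, Ifit3 11.7-fold and Usp18 10.96-fold. The fit of siStat3 and siCONTROL alone called 204 genes and DESeq2 548, where the pooled edgeR fit called 450.

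Interferon response genes rose in 17 of 20 with siStat3 (19 over the list alone, median log2 fold change 2.21, camera adjusted p = 1.58e-27, adjusted p = 0.0506 with an estimated correlation), including Rsad2, the antiviral enzyme viperin, 9.54-fold and Xaf1 3.25-fold. STAT3 and cytokine response genes fell in 3 of 17 and rose in 1 (7 and 2 over the list alone, median -0.45, camera 5.11e-05, and 0.0215 with an estimated correlation), with Il4ra 1.57-fold and Osmr 1.53-fold lower and Pim1 1.36-fold higher. Regeneration-associated genes, which include Stat3, fell in 9 of 26 (16 over the list alone, Sprr1a 1.69-fold, Klf7 1.26-fold, camera 9.93e-10, adjusted p = 0.00638 with an estimated correlation and 2.01e-05 without the targeted genes). Nociceptor markers rose in 2 of 16, Calcb 1.75-fold and Tac1 1.64-fold (3 over the list alone, camera 0.0131, adjusted p = 0.447 with an estimated correlation). Cholesterol synthesis genes fell in 1 of 20 (Msmo1 1.33-fold, camera 0.00382, adjusted p = 0.479 with an estimated correlation), pan-neuronal markers in 2 of 15 (5 down and 1 up over the list alone, Rbfox3 1.36-fold, camera 0.0447, adjusted p = 0.652 with an estimated correlation), and stress response regulators rose in 1, Sesn2, and fell in 1, Atf3, of 17 (camera 0.0458, adjusted p = 0.543 with an estimated correlation).

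With siKlf6 105 genes rose and 170 fell, 59 and 10 of them at least 2-fold. Interferon response genes were among those that rose. Ifit1 rose 19.95-fold (88.1 ± 95.0 against 4.46 ± 1.22 CPM, adjusted p = 0.000371), the chemokine Ccl5 12.4-fold, Ifi211 10.4-fold, Ifit3 10.3-fold and Usp18 9.88-fold, each with an SD near or above its mean. Interferon response genes rose in 18 of 20 (19 over the list alone, Rsad2 7.47-fold, Ddx58 3.21-fold, median log2 fold change 2.46, camera adjusted p = 2.98e-25, adjusted p = 0.0679 with an estimated correlation). Of genes that fell, F2r, the thrombin receptor, was 2.31-fold lower (adjusted p = 7.7e-05), the ATP synthase subunit Atp5g1 2.15-fold (272 against 587 CPM, adjusted p = 3.27e-09), the calcineurin subunit Ppp3cc 2.03-fold (adjusted p = 2.11e-08) and Gal3st1 2.02-fold. The KLF family fell in 1 of 13, Klf6 itself (camera 0.0461, adjusted p = 0.246 with an estimated correlation and 0.522 without the targeted genes), and regeneration-associated genes in 4 of 26 (5 down and 1 up over the list alone, Klf6, Hspb1 1.48-fold, Tnfrsf12a 1.36-fold, Tubb6 1.28-fold, camera 0.104). The number of genes called depended on the fit and on siKlf6 replicate 4. The fit of siKlf6 and siCONTROL alone called 18 genes, 1 of them higher, and 0 of 19 interferon genes. Without replicate 4, 160 genes in all and 5 of 20 interferon genes passed. The lowest siKlf6 library (408 CPM summed over the interferon list) still lay above the highest siCONTROL library (268 CPM).

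The summed level of the interferon list, which holds Ifit1 and Rsad2, was 227 ± 28.8 CPM in siCONTROL, 1172 ± 653 in siStat3 (589 to 1982) and 1014 ± 830 in siKlf6 (408 to 2223). In the other knockdowns the sums were 219 ± 28.1 CPM with siRest, 299 ± 72.5 with siJun, 306 ± 104 with siAlyref, 316 ± 20.5 with siAtf4 and 345 ± 140 with siAtf3. In the mRNA groups, where 18 of the 20 genes were tested, the sums were 232 ± 37.7 with GFP, 349 ± 62.5 with Atf4 and 358 ± 64.1 with Atf4 and Cebpg.

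**Figure D2:**
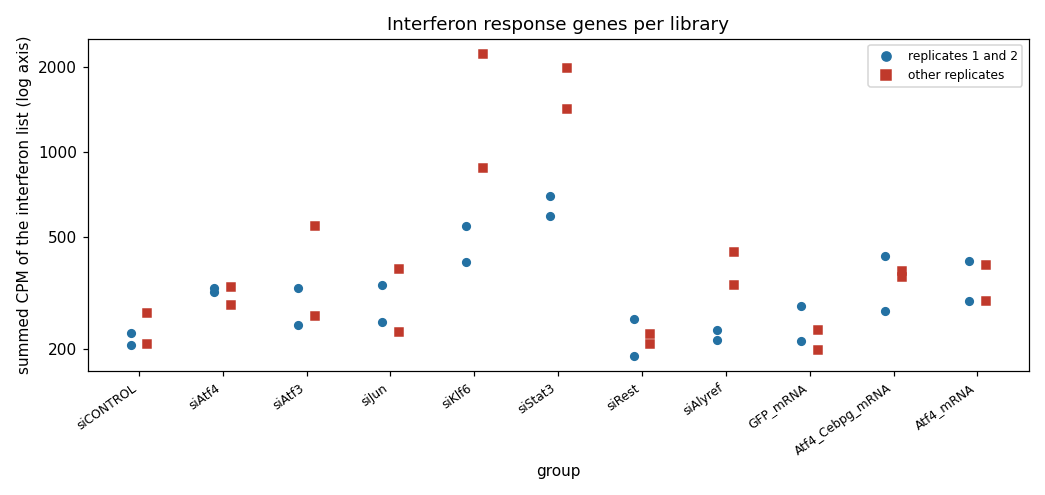
Summed CPM of the interferon response list in each library of each group (20 genes in the siRNA groups, 18 in the mRNA groups), on a log axis. Blue circles are replicates 1 and 2 and red squares all other replicates.

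Few genes were called with siRest. This low count cannot tell little dependence on Rest from a partial knockdown or from low power. Rest transcripts stayed at 36.3% of control (3.30 against 8.46 CPM), and siRest replicate 1 held only 1937372 counts. With siRest 2 rose and 28 fell of 14876 tested, 908 had an unadjusted p under 0.05, and 0 genes met the rule for naming a higher gene. Limk1, the kinase that inactivates cofilin, fell 1.91-fold (53.7 against 103 CPM, adjusted p = 3.38e-06), the membrane protein stomatin (Stom) 2.37-fold (adjusted p = 0.00235), the alanine transaminase Gpt2 1.90-fold (adjusted p = 0.0031) and the DNA repair protease Sprtn 1.87-fold (adjusted p = 0.0408). Neuronal genes with an RE1 site passed in 0 of 26 by edgeR, with Chrnb2 at 46.6 against 39.4 CPM (adjusted p = 0.727), and did not pass as a set (camera adjusted p = 0.332). AP-1 and immediate early genes passed in 0 of 16 singly but were lower as a set (median log2 fold change -0.17, camera 0.00725, adjusted p = 0.202 with an estimated correlation). The count of 30 became 47 by DESeq2, 18 without a filter and 5 with siRest and siCONTROL alone. It was 16 and 15 without siCONTROL replicates 1 and 3, and 17, 18 and 16 without siRest replicates 1, 2 and 3.

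Most genes called with siAlyref were lower: 131 rose and 502 fell (79.3% lower), 4 and 47 at least 2-fold. Alyref is an adaptor that couples mRNA processing to nuclear export, which was not measured here. Eif3b, a subunit of the translation initiation factor eIF3, fell 3.11-fold (89.0 ± 14.8 against 278 ± 16.4 CPM, adjusted p = 2.54e-13), the actin-binding protein advillin (Avil), a marker of sensory neurons, 2.32-fold (349 against 810 CPM, adjusted p = 2.54e-13), the lipid flippase Atp11a 2.68-fold (adjusted p = 1.03e-07), Tmem140 4.05-fold and Pemt 3.04-fold. The imprinted gene Rtl1 rose 4.12-fold (17.6 against 4.19 CPM, adjusted p = 1.39e-07), Nr6a1 1.96-fold, Lrch2 1.80-fold, Tceal1 1.74-fold and Dgkg 1.74-fold. The fit of siAlyref and siCONTROL alone called 352 genes.

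Regeneration-associated genes fell in 5 of 26 with siAlyref (7 over the list alone, Sox11 1.90-fold, Sema6a 1.597-fold, Smad1 1.33-fold, Klf6 1.40-fold, camera adjusted p = 1.06e-05, adjusted p = 0.0506 with an estimated correlation) and pan-neuronal markers in 3 of 15 (5 over the list alone, Avil, Tubb3 1.29-fold, Elavl3 1.28-fold, camera 0.000615, adjusted p = 0.400 with an estimated correlation). Amino acid transporters fell in 3 of 10 (3 down and 1 up over the list alone, Slc38a1 1.42-fold, Slc7a1 1.33-fold, camera 0.0215, adjusted p = 0.0930 with an estimated correlation) and p53 targets in 2 of 18, Cdkn1a 1.54-fold and Aen 1.26-fold (camera 0.0491, adjusted p = 0.387 with an estimated correlation). Of 14 TREX factors 1 fell, Alyref itself (2 over the list alone, camera 0.865).

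**Figure D3:**
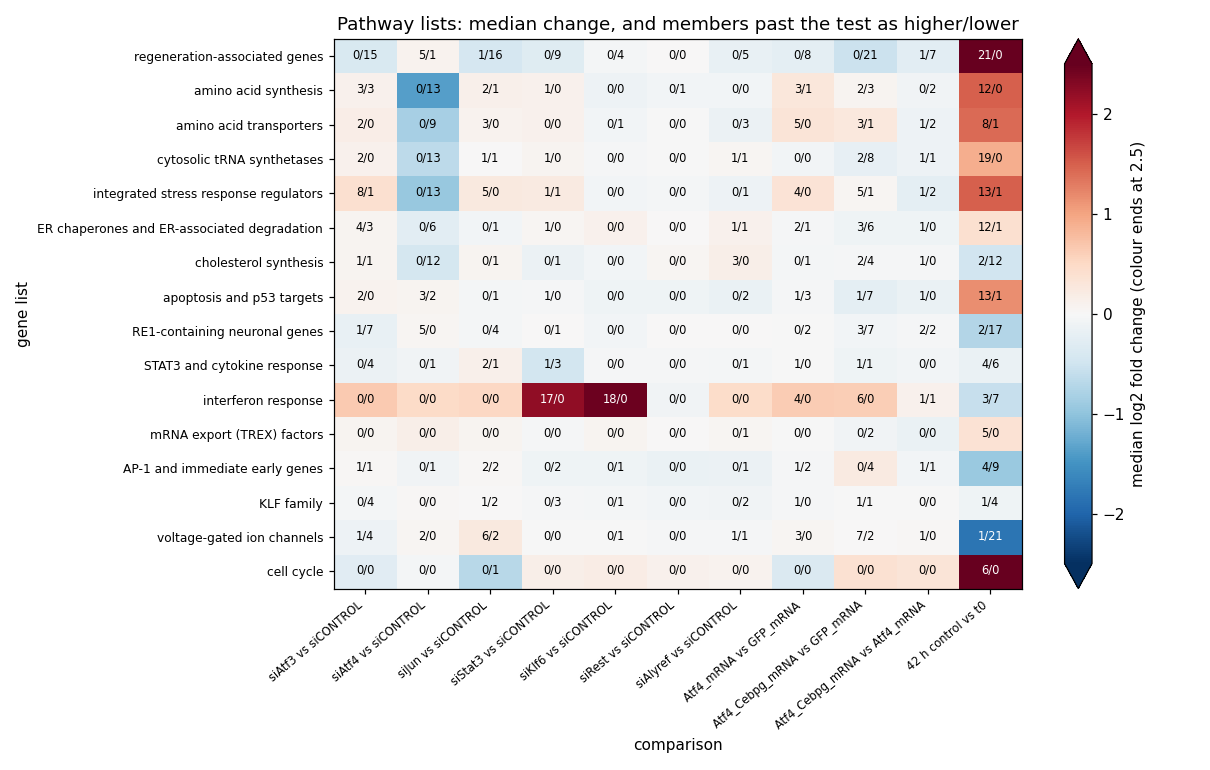
Median log2 fold change of 16 pathway lists (vertical) in 11 comparisons (horizontal), with the colour scale ending at 2.5 in each direction. Text in each field gives the numbers of list members that passed as higher and as lower.

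Atf3 and Jun knockdowns were compared gene by gene with the other knockdowns. Genes lower with both siAtf3 and siJun numbered 336 where 51.1 were expected from independent lists, Sprr1a, Aim2 and Fgf3 among them, and 144 were higher with both where 19.0 were expected. The correlation of log2 fold changes was 0.510, but unchanged groups simulated against the same 4 controls gave 0.508, and with the controls split it was 0.107. The covariance was 0.191 against 0.124 in the simulations. For siAtf3 and siAtf4 the correlation was 0.243 (simulated 0.509; -0.0765 with the controls split), the covariance 0.0891 against 0.124, and 206 genes moved in opposite directions where 55.4 were expected. In the same direction, 68 were lower in both (46.4 expected) and 29 higher in both (16.3 expected). For siStat3 and siKlf6, 56 genes were higher in both, with Ifit1, Ifit3 and Usp18 among them, where independent lists would give 1.25. Their correlation was 0.417 (simulated 0.491; 0.0319 with the controls split). Shared controls raise the numbers that move together above those of independent lists. The simulations drew every library independently. Over the 21 pairs the correlation ran from 0.243 to 0.510, with a median of 0.401 (jackknife SE 0.177). The simulated one ran from 0.488 to 0.516. With the controls split the median was 0.0112.

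Genes that changed in culture were then followed in each knockdown. With siJun, 726 of 901 genes called in both comparisons moved opposite to their change in culture (80.6%, 95% interval 77.9 to 83.0; 80.5% with the controls split), among them Sprr1a and Scn10a. The shares were 71.9% with siAtf4 (526 of 732; 74.8% with the controls split), 67.9% with siAlyref (303 of 446; 66.3%), 63.1% with siStat3 (207 of 328; 64.6%), 58.8% with siKlf6 (110 of 187; 57.8%) and 53.8% with siAtf3 (616 of 1145; 51.4%). With siRest it was 68.8% (11 of 16, interval 44.4 to 85.8) and 47.4% with the controls split. Because siCONTROL enters both comparisons with opposite sign, noise alone gives a negative correlation: for siJun it was -0.382 against -0.118 in simulated unchanged groups, with a covariance of -0.175 against -0.0371. It was -0.190 against -0.114 for siAlyref, -0.172 against -0.116 for siAtf3, -0.152 against -0.114 for siStat3 and -0.15 against -0.118 for siAtf4. For siKlf6 (-0.107 against -0.111) and siRest (-0.0562 against -0.112) the correlation did not exceed that of unchanged groups. Their covariances were -0.0452 against -0.0357 for siKlf6 and -0.021 against -0.0358 for siRest.

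Transfected mRNA raised Atf4 transcripts far above their endogenous level. Atf4 reached 14140 ± 3900 CPM with Atf4 mRNA against 642 ± 53.6 with GFP (22.0-fold, log2 fold change 4.46 ± 0.319 SE, adjusted p = 6.83e-06) and 20850 ± 9610 with Atf4 and Cebpg mRNA (32.5-fold, adjusted p = 3.21e-07). Cebpg rose from 46.6 ± 5.72 to 61200 ± 23100 CPM with both mRNAs (1313-fold, log2 fold change 10.36 ± 0.284 SE, adjusted p = 6.48e-11) and was 52.4 CPM with Atf4 mRNA alone (adjusted p = 0.746). Between the groups that received it, Atf4 was 1.47-fold higher with both mRNAs, a difference that did not pass (log2 fold change 0.56 ± 0.277 SE, adjusted p = 0.271). A difference in Atf4 dose is not excluded. Synthetic and endogenous transcripts cannot be told apart in gene-level counts.

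With Atf4 mRNA, 382 genes rose and 289 fell of 13857 tested, 159 and 43 at least 2-fold. Cth, which makes cysteine from cystathionine, rose 4.96-fold (37.4 against 7.49 CPM, adjusted p = 7.6e-07), Csn3 15.6-fold, Fbxo47 8.92-fold, Pcdh20 8.73-fold (adjusted p = 9.08e-06), Mettl7b 6.80-fold (adjusted p = 6.83e-06), the acute-phase gene Saa3 6.14-fold, Krt1 6.01-fold, Rwdd2a 5.38-fold, Tnfrsf19 5.35-fold and Cspg5 5.30-fold. Neuropeptide Y (Npy) fell 6.81-fold (9.61 against 64.9 CPM, adjusted p = 0.00361), Csrp3 6.12-fold, Rasal1 5.06-fold, Pilra 4.11-fold, Aim2 3.87-fold, Sprr1a 2.56-fold (130 against 334 CPM, adjusted p = 1.27e-05), Inhba 2.53-fold (adjusted p = 0.00628), Ccdc172 2.49-fold, Areg 2.40-fold and Ucn 2.31-fold. The total of 671 was 925 by DESeq2. It became 410, 411 and 442 without GFP replicates 1, 2 and 4, and 389 and 339 without Atf4 mRNA replicates 2 and 4.

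Amino acid transporters rose in 5 of 10 with Atf4 mRNA (6 over the list alone, Slc7a11 2.25-fold, Slc7a3 1.78-fold, camera adjusted p = 4.71e-05, adjusted p = 0.148 with an estimated correlation), stress response regulators in 4 of 17 (6 up and 1 down over the list alone, Stc2 3.62-fold, Sesn2 2.39-fold, Chac1 1.46-fold, camera 0.00018, adjusted p = 0.179 with an estimated correlation) and amino acid synthesis genes in 3 of 13 with 1 lower (5 and 2 over the list alone, Cth, Aldh1l2 1.93-fold, Shmt2 1.24-fold higher, Got1 1.27-fold lower, camera 0.00705, adjusted p = 0.127 with an estimated correlation). Of 20 tRNA synthetases 0 passed by edgeR, and the set did not pass by camera (0.210); Mars stood at 60.5 against 45.9 CPM (adjusted p = 0.0839). Nociceptor markers rose in 4 of 16 (8 over the list alone, Mrgprd 5.87-fold, Tac1 1.95-fold, Scn11a 1.87-fold, Scn10a 1.49-fold, camera 3.01e-06, adjusted p = 0.241 with an estimated correlation) and interferon response genes in 4 of 18 (6 over the list alone, Isg15 2.98-fold, Cxcl10 2.58-fold, Rsad2 2.21-fold, camera 0.000121, adjusted p = 0.421 with an estimated correlation). Regeneration-associated genes fell in 8 of 24 (11 over the list alone, Sprr1a, Hspb1 1.68-fold, Jun 1.41-fold, camera 1.47e-08, adjusted p = 0.190 with an estimated correlation).

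The response to both mRNAs was wider than that to Atf4 mRNA alone, and an effect of Cebpg was not separated from a higher dose of Atf4. Against GFP, 1725 genes rose and 1689 fell with both mRNAs, 738 and 142 at least 2-fold. Apela, a peptide ligand of the apelin receptor, had 0 counts in every GFP library and 38.1 ± 6.39 CPM with both mRNAs (at least 114-fold). Akr1c18 rose at least 47.3-fold, and the LIM-domain factor Lmo3 went from 0.330 ± 0.55 to 57.4 ± 1.28 CPM (172-fold, adjusted p = 5.63e-08). Lrrc17 rose 27.5-fold and autotaxin (Enpp2) 25.6-fold (adjusted p = 4.56e-08). The somatostatin receptor Sstr1 rose 24.9-fold from 0.698 ± 0.696 CPM and Enpp3 19.8-fold from 0.917 ± 0.684 CPM, and Treml4 went from 0.0524 to 12.98 CPM. Folds from such low levels are imprecise. Pilra fell 6.20-fold, Aim2 5.45-fold, Npy 5.17-fold, Csrp3 4.59-fold, Pla2g3 4.52-fold, Inhbb 4.32-fold, Fgf3 4.15-fold, Cryba2 3.95-fold, Lipn 3.92-fold and Prss37 3.83-fold.

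Of 24 regeneration-associated genes, 21 fell with both mRNAs (22 down and 2 up over the list alone, Sprr1a 3.77-fold, Hspb1 2.16-fold, Atf3 1.85-fold, Jun 1.68-fold, camera adjusted p = 2.49e-09, adjusted p = 0.165 with an estimated correlation). Nociceptor markers rose in 9 of 16 (12 over the list alone, Mrgprd 8.02-fold, somatostatin (Sst) 6.999-fold, Scn11a 2.33-fold, camera 3.18e-05, adjusted p = 0.305 with an estimated correlation). Interferon response genes rose in 6 of 18 (Isg15 4.01-fold, camera 0.00156, adjusted p = 0.520 with an estimated correlation) and endothelial and mural markers in 3 of 11 (4 over the list alone, Cdh5 1.52-fold, Pecam1 1.502-fold, camera 0.00595, adjusted p = 0.599 with an estimated correlation). Cytosolic tRNA synthetases fell in 8 of 20 and rose in 2 (9 and 2 over the list alone, Wars 1.30-fold lower, camera 0.0403, adjusted p = 0.554 with an estimated correlation). Amino acid synthesis genes rose in 2 and fell in 3 of 13 (Cth 44.9 against 7.49 CPM, Got1 1.47-fold lower, camera 0.674), transporters rose in 3 and fell in 1 of 10 (Slc7a3 2.84-fold higher, camera 0.0599), and stress response regulators, which include Cebpg, rose in 5 and fell in 1 of 17 (Sesn2 2.85-fold higher, Atf3 lower, camera 0.249).

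Set directly against Atf4 mRNA alone, both mRNAs gave 624 higher and 291 lower genes, 289 and 17 at least 2-fold. Sstr1 stood at 18.2 against 0.429 ± 0.601 CPM (42.4-fold), too low a level for a precise fold. Lmo3 was 31.2-fold higher (57.4 against 1.78 CPM), Akr1c18 at least 40.8-fold, and Apela stood at 38.1 against 0.206 CPM. Star was 7.01-fold lower (25.8 against 182 CPM, adjusted p = 1.59e-06), Prss37 6.85-fold, Ptx3 3.27-fold, Mmp19 2.41-fold and Cryba2 2.35-fold. Regeneration-associated genes were lower in 7 of 24 and higher in 1 (12 and 1 over the list alone, Atf3 1.48-fold, Sprr1a 1.47-fold lower, camera adjusted p = 0.000137, adjusted p = 0.419 with an estimated correlation), and endothelial and mural markers were higher as a set with 0 of 11 passing singly by edgeR (camera 0.0185, adjusted p = 0.652 with an estimated correlation). Stress response regulators had an adjusted p of 0.117 (0.0249 without the targeted genes), with Chac1 1.47-fold lower. The total of 915 was 575 and 553 without replicates 2 and 4 of the group with both mRNAs.

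Atf4 knockdown and Atf4 overexpression share no library. Of genes lower with siAtf4, 54 were higher with Atf4 mRNA where 15.2 were expected, among them Chac1, Sesn2, Slc7a1, Slc7a3, Shmt2, Adm2, Vegfa and Atf4 itself. Inhba and Pmaip1 were among 31 genes higher with siAtf4 and lower with Atf4 mRNA, where 8.42 were expected. In the same direction, 22 were lower in both (13 expected) and 5 higher in both (9.84 expected). Over 13665 genes the correlation was -0.128 (jackknife SE 0.0726), and over 1529 genes called in either it was -0.251. With both mRNAs the correlation was -0.0393; 98 genes were lower with siAtf4 and higher with the mRNAs (71.2 expected), 103 the reverse (49.2 expected), 158 lower in both (76.1 expected) and 28 higher in both (46.0 expected).

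**Figure D4:**
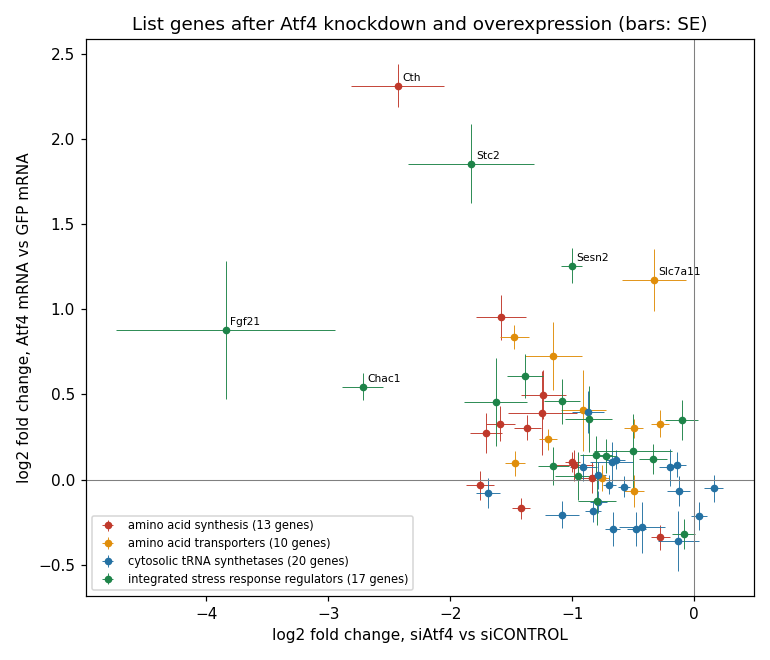
Log2 fold change with siAtf4 (horizontal) against log2 fold change with Atf4 mRNA (vertical) for genes of amino acid synthesis, amino acid transport, tRNA charging and the integrated stress response. Bars are standard errors, from 4 libraries per group.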

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

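The tests of macrophages, of the replicate split and of the siRNA pools for the interferon genes, of depth for the genes detected, and of transfected cultures as a source of Cebpg were chosen only after those results were seen. The tests of an even background and of the stress response genes were set before theirs were.

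Among 71 groups of 4 values tested for a library far from its group (Dixon gap over range, 95% critical value), 4 held one, and chance alone marks about 1 in 20 groups. Time 0 replicate 4 had 16979 genes above 0 counts against 17184 to 17189 in the other 3 libraries. The shallow siRest replicate 1 had 15975 against 17868 to 18192. Cebpg stood at 187.7 CPM in siKlf6 replicate 5 against 29.8 to 52.6 in the other siKlf6 libraries, and at 87.1 CPM in siStat3 replicate 2 against 45.6 to 52.3.

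Cebpg encodes the dimer partner that was transfected in other cultures of the series, so the siKlf6 library was looked at more closely. Against the mean of the other 3 siKlf6 libraries it held 144 CPM more Cebpg and 158 CPM more Atf4 (their Atf4 SD 16.3). Its Atf4 level, 635 CPM, lay within the range of the siStat3 (552 to 670) and siJun libraries (550 to 664). It was above the highest siCONTROL library (606) and the highest library of each other knockdown. RNA or reads from a culture given both mRNAs would have brought 34.6 to 60.2 CPM of Atf4, less than was seen, so this source accounts for part of the Atf4 excess at most and cannot be told apart from a rise in the cells. For a stronger integrated stress response in that library, a median log2 difference above 0.5 had been asked of 43 genes of amino acid supply and tRNA charging. The median was 0.0831 (SD 0.19, 30 higher and 13 lower), which argues against a rise of that size. A smaller rise is left open. No other biological explanation was tested.

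Interferon response genes were higher with siStat3 and siKlf6 (median log2 fold changes 2.21 and 2.46), but the list did not pass with an estimated correlation (adjusted p = 0.0506 and 0.0679). By edgeR the number of genes called with siKlf6 fell to 0 of 19 in a fit with siCONTROL alone and to 5 of 20 without siKlf6 replicate 4. With siStat3, 16 of 19 were called alone and 15 to 17 of 20 without any 1 library. The 4 macrophage markers tested had medians of -0.20 and -0.07, at least 2.41 below the interferon medians, so they did not rise as a list. Their changes differed widely from marker to marker (SD 0.887 with siStat3 and 1.37 with siKlf6), and in culture macrophage markers moved in both directions. So few markers that do not move together cannot decide whether more macrophages were the source. Across the siRNA groups, residual correlation between different replicate numbers averaged 0.021 within replicates 1 and 2 or within the others, and -0.046 between these parts. The labels give no reason for it. Each group is divided evenly over the 2 parts, so this split could not by itself raise a knockdown over its control. Within the 2 parts the lowest siStat3 or siKlf6 library had 1.8 and 3.28 times the interferon sum of the highest siCONTROL library. Loss of Stat3 or Klf6 may release interferon signalling, or these siRNA pools may themselves be sensed as foreign RNA. With 1 pool per target gene the 2 cannot be told apart.

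More genes were detected after Atf4 and Cebpg mRNA: thinned to 1500000 counts, these libraries held 17536 ± 514 genes, against 16446 ± 102 with Atf4 mRNA and 16089 ± 53.3 with GFP. At that common depth the lowest of them exceeded the highest GFP library by 627 genes, which argues against depth. Of 8093 genes of known length at 0 in every siRNA and time 0 library, 29 (Apela, Hoxb1, Hand1 and Atoh1 among them, named after their values were seen) were found in all 4 libraries with both mRNAs where independent hits would give 0.0492, a ratio of 589, and 0 were with GFP or with Atf4 mRNA alone. With Atf4 mRNA alone, Hoxb1 was still found in 3 of the 4 libraries, Apela and Hand1 in 2 each and Atoh1 in 0. The ratio of 589 argues against an even background such as genomic DNA as the whole cause. But with 183 to 467 of the 8093 genes hit per library (38 to 67 with GFP) and 53 to 124 olfactory or vomeronasal genes (42 to 51 with GFP), a background may hold part of the excess. Wider opening of silent genes by an excess of the ATF4 and CEBPG proteins may be a cause, and reads of the synthetic transcripts placed on other genes were not tested.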

How the results depend on the processing

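The term for replicates 1 and 2 against the others, the fits without the shallow libraries or without Atf4 and Cebpg in the scaling, and the lists without targeted genes were chosen after seeing the data. For targeted and transfected genes, 182 values kept their direction and their side of the threshold. The exception was Rest with siRest and siCONTROL fitted alone (log2 fold change -1.45, adjusted p = 0.275, and 9.48e-06 to 0.00213 under the other alternatives), a fit that estimates the spread from fewer libraries. Of the counts of genes changed, 164 stayed within 1.5 times the value reported and 22 did not. With median-ratio size factors, the stricter filter and limma-voom all 11 counts stayed within it, as they did with each alternative added later (siRest 37 with the replicate term and 23 without the shallow libraries, siKlf6 370 and 253, siStat3 567 with the term). The siRest count of 30 became 18 with no filter and 47 by DESeq2, and the cause was not tested. With only the groups compared, siStat3 gave 204 genes, siKlf6 18, siRest 5 and siAlyref 352. A replicate block gave 751 for siStat3, 46 for siRest and 1028 for Atf4 mRNA, and the cause was not tested. The pseudocount alternatives were not run, since the values are counts.

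Leaving out each library in turn gave 1313 to 1552 genes for siAtf3, 753 to 866 for siAtf4, 877 to 1034 for siJun, 335 to 428 for siStat3, 443 to 508 for siAlyref, 2685 to 3329 for both mRNAs against GFP and 7385 to 7599 for culture. For siKlf6 it gave 160 to 284, lowest without siKlf6 replicate 4. For siRest it gave 15 to 24, with 16 and 15 without siCONTROL replicates 1 and 3 and 17, 18 and 16 without siRest replicates 1, 2 and 3. For Atf4 mRNA it gave 339 to 572, with 410, 411 and 442 without GFP replicates 1, 2 and 4 and 389 and 339 without Atf4 mRNA replicates 2 and 4. For both mRNAs against Atf4 mRNA it gave 553 to 961, with 575 and 553 without replicates 2 and 4 of the group with both. Of 63 list tests past the threshold, 13 passed with an estimated correlation, 61 with a replicate block (82 in all), 53 by fry (77 in all) and 61 without the targeted genes (62 in all). The correlation between Atf4 knockdown and overexpression was -0.251 over genes called in either, against -0.128 over all. The median correlation between knockdowns was 0.0112 with the controls split, against 0.401 with shared controls, which add a common term to both sides. The siRest share opposite to culture reversed from 68.8% to 47.4% with the controls split, and the cause was not tested. In simulated data 22.4% to 43.3% of genes changed 1.5-fold were recovered, so small changes are missed at this depth and group size.

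The libraries were not treated as paired. Across siRNA groups, libraries of the same replicate number had a mean residual correlation of 0.075 over all genes and 0.13 at a mean of at least 5 CPM (20 and 78 of 105 pairs above 0.1), across mRNA groups 0.11 and 0.14 (7 and 9 of 12) and in culture 0.089 and 0.074 (1 and 1 of 4). A replicate block gave 1620 genes for siJun, against 1157 without it. Over all genes, 29 of 32 siRNA libraries, 12 of 12 mRNA libraries and 7 of 8 in culture correlated best with their own number. Among the siRNA libraries, siKlf6 replicate 5 could not do so, since no other group has a library of that number. Libraries of the same number thus resembled each other across groups. Shared preparations would give this, though the labels do not name any, and the main counts of genes changed do not allow for it. If replicate numbers mark shared preparations, only swaps within a number are free. These are too few to exclude chance by splits of the libraries.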

Other observations

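The genes named in the next 2 paragraphs were chosen after their values were seen, from the members of the fixed lists. Knockdowns moved single sensory and stress genes apart from the lists that hold them. P2rx3, the ATP-gated channel of nociceptors, was 1.99-fold lower with siAtf4 (242 against 482 CPM, adjusted p = 2.54e-06), and Calcb, which encodes a calcitonin gene-related peptide, was 1.73-fold lower with siKlf6 (257 against 444 CPM, adjusted p = 8.78e-05) and 1.39-fold lower with siAtf4 (adjusted p = 0.0071). With siAtf3 the nociceptor sodium channel Scn9a fell 1.47-fold (adjusted p = 5.26e-06) and the calcium channel Cacna1b 1.77-fold (adjusted p = 7.93e-05), while the ER chaperone Hspa5 rose 1.55-fold (adjusted p = 2.4e-07). With siJun the immediate early genes Egr1 and Junb rose 1.80-fold (adjusted p = 3.07e-05) and 1.73-fold, and Klf9 fell 1.75-fold (adjusted p = 1.47e-06). With siAlyref the ER co-chaperone Dnajb9 fell from 60.0 to 29.9 CPM (adjusted p = 3.37e-06).

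Single genes moved with overexpression as well. Dnajb9 rose 1.81-fold with Atf4 mRNA (adjusted p = 0.000184) and 2.91-fold with both mRNAs (adjusted p = 1.51e-07). Glul, the glutamine synthetase, fell 1.64-fold with Atf4 mRNA (adjusted p = 0.00546) and from 367 to 158 CPM with both (adjusted p = 1.72e-05). With both mRNAs the neuronal tubulin Tubb3 was also lower (1513 against 2418 CPM, adjusted p = 1.76e-05), while the sodium channel Scn1a rose 4.08-fold (adjusted p = 0.000469), the ETS factor Etv1 2.96-fold (adjusted p = 0.000877) and the cholesterol carrier Stard4 2.32-fold (adjusted p = 1.27e-05). The noxa gene Pmaip1, higher with siAtf4, was 2.22-fold lower with Atf4 mRNA (adjusted p = 0.00584).

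Every way of splitting the 8 libraries of a comparison into 4 and 4 was tried, a test set before the results were seen. In each of the 11 comparisons 1 of 35 splits, the real one, gave as many genes, the smallest share that these splits allow. The splits take the 8 libraries as independent, which the correlations by replicate number put in doubt. They therefore do not exclude chance as the source of a count, and they say nothing of any single gene. Mixed splits hold the real difference within both sides, which lowers their counts, and the test covers the pooled fit: siKlf6 and siRest fitted alone with siCONTROL gave 18 and 5 genes. The real count and the highest of the other splits were 1709 and 1 for siAtf3, 1028 and 1 for siAtf4, 1157 and 1 for siJun, 450 and 2 for siStat3, 275 and 1 for siKlf6, 30 and 1 for siRest and 633 and 2 for siAlyref. They were 671 and 1 for Atf4 mRNA, 3414 and 0 for both mRNAs against GFP, 915 and 1 for both against Atf4 mRNA, and 7781 and 2 for culture.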
